A study of Drosophila melanogaster with 16 samples.

How the data were processed

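Embryos of the yw line were collected for 45 min at 25 °C and aged for 2 h to enrich for nuclear cycle 14. They were crosslinked with formaldehyde and then with DSG and EGS, staged by hand, and digested with micrococcal nuclease, per the labels' protocols. Libraries were sequenced with 50 bases per mate. Reads were aligned to the dm6 build with BWA 0.7.17, per the submitters' processing notes. The other steps from reads to contact maps are not given in the sources used here, and neither is whether the 2 control samples were pooled before features were called.

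The 3 files used here all hold features of the yw line, without a column per sample. The boundary list gives bins of 400 bp, each with a strength. This strength is a score deposited by the authors, and the scale and window of the insulation measure behind it are not given in the sources used here. The loop table carries the column names of the SIP loop caller per the file headers, and its loop value and further scores were deposited by the authors with no stated scale or matrix normalization. The anchor list gives 626 anchors of the 313 loops, each with the score of its loop as deposited. Scores were used only within a list, to describe, rank or split features, to test differences in score between groups of features, and to relate loop value to span. No read counts were used, so the depth behind each feature is unknown, and a loop or boundary missing from a list is not shown to be missing from the chromatin.

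Of 2034 boundary entries, 14 were exact repeats and were removed, which left 2020. Of these, 90 lay on Y and were kept out of the comparisons, and 1930 lay on the 6 compared arms. The 626 anchors made 614 different intervals, 354 of 400 bp and 260 of 800 bp, the same 614 as in the loop table. Anchors that touched were joined for counts of loops per anchor, giving 585, of which 39 took part in 2 loops and 1 in 3. Arm lengths were taken as the last coordinate of a gene, boundary or loop.

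Genes came from a RefSeq gene table of Release 6 of the genome assembly, the same assembly as dm6, with 13922 protein-coding genes on the compared arms. The table used here has no strand, so transcription starts could not be placed. The planned distance to a start was replaced by the distance to either end of a protein-coding gene, within 1 kb. A gene end near a feature can thus be the 3' end of the gene. The planned test of sequence motifs and the use of a single start per gene were not run, since no genome sequence or strand was used here.

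The 19 gene lists were written before the data were examined, as were the tests and the rule for named genes. They comprise 11 developmental lists (Hox, other genes of the Antennapedia complex, gap and head, pair-rule, segment polarity, dorsoventral, neural, paired or clustered transcription factors, other developmental transcription factors, ligands, and early zygotic genes of cellularisation and sex determination), 4 housekeeping lists (ribosomal, mitochondrial ribosomal, proteasome, oxidative phosphorylation) and 4 late tissue-specific lists (chemoreceptor, cuticle, odorant binding, Osiris). Housekeeping and late lists were filled by symbol patterns, which also took in paralogs such as RpLP0-like and, in the cuticle list, the reductase gene Cpr. Listed symbols that the table gives under other names were matched by synonym: hairy as hry, Hr46 as Hr3, frs as Z600 and the Notch ligand Dl as Delta. The last was set by hand, after the values were seen, because the table gives the symbol Dl as a synonym of dorsal too. All listed genes were found.

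Named are every gene of the Hox list and of the other genes of the Antennapedia complex, and for each other list up to 5 members at anchors by loop value and up to 5 at boundaries by strength. Further named are genes at anchors of the 10 loops of highest value, of the 5 longest loops and of anchors with 3 or more loops, and genes at the 10 strongest boundaries. Genes in which an anchor or boundary lies, or that are nearest to it, are given to place the feature. Not every gene that the rule allows is printed, and 1 item withheld for evaluation is not reported here. Genes named outside the rule are marked as chosen after their values were seen, as are list members given to complete a small count.

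Positions were tested by circular shifts of the features along each arm in whole bins, 100000 times, two-sided, so the smallest p is 2e-05. Overlap meant at least 1 bp. A loop spanned a boundary when the boundary lay wholly between the inner edges of the anchors. Differences in median score used 100000 permutations, with a smallest p of 1e-05. Gene lists were tested by two-sided Fisher's exact tests against all other protein-coding genes of the compared arms, with Benjamini-Hochberg adjustment over the 19 lists, and separately over the 3 classes. Genes in a cluster are not independent, and Fisher's test does not account for this. Partners of anchors were permuted within an arm for the pairing of gene ends. X was compared with autosomes by 100000 draws of the count on X by arm length, in place of the planned draws over all arms. Intervals of shares are 95% Wilson intervals and treat features as independent. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

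The tests were checked on simulated data. With no planted effect, 1 of 40 simulated anchor sets, 3 of 40 loop sets, 1 of 40 gene lists of 60 members at boundaries and 0 of 40 strength comparisons of 20 boundaries passed a threshold of 0.05. With 5% of the 614 anchors placed on boundaries, 50% of the 313 loops kept inside domains, odds of 4 for a list, or a shift of 0.5 in log2 strength, all 40 passed in each case. Members of the simulated lists were drawn independently, so this check does not cover lists of neighbouring genes.

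Alternatives fixed in advance were other overlap distances, stronger boundaries, loops of higher value, uniform placement, each arm left out, gene-end placement, classes of loop span or gene spacing, other score columns and other arm lengths. Added after the data were seen were the removal of centromere-proximal features, the removal of boundaries whose strength equals that of another boundary, the mean difference over classes of loop span (with and without centromere-proximal loops), and counting list members within 200 kb of each other as 1 unit or by 1 drawn member. Both ways of counting neighbouring list members were run at anchors only. The centromere-proximal parts were set as above 22 Mb on 2L, 23 Mb on 3L and 22.5 Mb on X, and below 5.5 Mb on 2R and 4.5 Mb on 3R.

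The 14 samples of edited genotypes were not analysed here. The labels number 2 samples ScrEE1 and ScrEE2, which were kept as separate groups of 1 because their genotype labels differ.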

Results

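Chromatin contacts were mapped in staged Drosophila melanogaster embryos by Micro-C, a form of chromosome conformation capture in which crosslinked chromatin is cut between nucleosomes by micrococcal nuclease before ligation. The 16 samples came from embryos of nuclear cycle 14, the stage at which the blastoderm cellularises and zygotic transcription becomes widespread. The 2 control samples carried the yw background. The other 14 samples carried edited genotypes, most of them with a Hox gene of the Antennapedia complex (Dfd, Scr or Antp) in the label, with 6 genotypes of 2 samples and 2 labels of 1 sample. The series labels describe the edited lines as deletions of architectural elements. The values below describe the control line alone: a list of insulation boundaries, a list of chromatin loops and the list of the loops' anchors. Each list holds a single value per feature, so no value has a replicate error, and the depth of the maps is unknown. The edited genotypes were not analysed here. All tests permute or count features within the control map, so their p-values concern the placement of features and not the spread between embryos.

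The control map held 2020 boundaries, each 400 bp wide, and 313 loops. On the 6 compared arms (2L, 2R, 3L, 3R, 4 and X) there were 1930 boundaries, and the distance between neighbours left domains with a median size of 36.4 kb and quartiles of 11.6 and 94.8 kb. Boundary strength, a score given by the authors, ran from 1.2502 to 9.50 on these arms with a median of 1.64. The label of the list names a minimum strength just below the lowest value, so weaker boundaries are not listed. The median strength, the domain sizes and each statement below that a boundary is absent depend on this cut. Loops spanned a median of 32.8 kb, with quartiles of 19.2 and 51.6 kb and a range of 6.80 to 239.6 kb. The deposited loop value had a median of 7.75 and ran from 4.26 to 653. Of 1895 domains, 215 (11.3%) held at least 1 whole loop, and 41 held 2 or more. Domains with a whole loop had a median of 110.4 kb and the 1680 without one 29.6 kb, an order set in part by the definition, since a domain smaller than the shortest loop cannot hold one. The domain sizes depend on the strength required of a boundary, and the domains between boundaries of at least the median strength had a median of 84.4 kb.

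Loops were denser on X than on the autosomes. X carried 79 loops, or 3.36 per Mb, against 2.13 per Mb over the autosomal arms, a ratio of 1.58 (two-sided permutation test, p = 0.00102). With the centromere-proximal parts left out, the ratio of loops was lower, at 1.45 (two-sided permutation test, p = 0.00722). Arm 2L had 2.90 loops per Mb, arm 2R 2.14, arm 3R 1.93, arm 3L 1.71 and chromosome 4 1.57. Boundaries differed less, with 15.8 per Mb on X and 14.1 per Mb on autosomes. This ratio of 1.12 did not pass the test (permutation p = 0.0549), although it did once the centromere-proximal parts were left out (ratio 1.14, permutation p = 0.0351).

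At the Antennapedia complex on 3R, the cluster of Hox genes that specifies head and anterior thorax, the control map held 12 boundaries and 4 loops. These lay between 6641427 and 7049228 (dm6), an interval that includes flanking sequence beyond lab and Antp. The loop of highest value joined the right end of Scr, at 6848801 to 6849200 inside the gene and 781 bp from its end, to an intergenic bin at 6893201 to 6893600 that lies 2653 bp from the left end of Antp. It spanned 44.4 kb and had a value of 49.7, rank 30 of the 313 loops. Between its anchors lay the pair-rule gene ftz (6864324 to 6866244), with a boundary on each side, at 6854401 (strength 1.43) and 6870801 (strength 1.58). The loop thus joined sequence near Scr to sequence near Antp across ftz and across both boundaries beside ftz. The other 3 loops spanned no boundary. A loop of value 6.95 ran 49.6 kb from 6708801, inside pb, to 6758401, inside the maternal anterior determinant bcd. It enclosed zen2 and zen. A loop of value 9.84 joined 6933201 and 6968801, both inside Antp. A loop of value 29.0 ran from 7000801, 1573 bp beyond the right end of Antp, to 7037201 in the flanking sequence.

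The strongest boundary of the complex lay inside Antp at 6912401, with a strength of 2.50 and rank 200 of 1930, and a weaker one of 1.43 lay beside it at 6908001. Other boundaries lay between the Hox genes. Dfd (6791836 to 6802428) stood between boundaries at 6780001 (strength 1.69) and 6806401 (1.85). The interval between Dfd and Scr held 2 further boundaries, at 6820001 (1.82) and 6822001 (1.67), the latter 720 bp from the left end of Scr (6823120 to 6849981). A boundary of strength 1.34 lay 135 bp from the right end of bcd, before Ama, which had no boundary or anchor within 1 kb. On the other side of pb, a boundary of strength 1.62 at 6683601 separated lab (6661427 to 6678590) from the cluster of cuticle genes that begins with Edg84A. A boundary of strength 1.37 at 6657601 lay on the other side of lab, and one of 1.79 at 6646401 was 89 bp from Taf1. The genes lab, pb, Dfd, Antp, zen, zen2, ftz and Ama had no anchor and no boundary within 1 kb of either end.

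**Figure D1:**
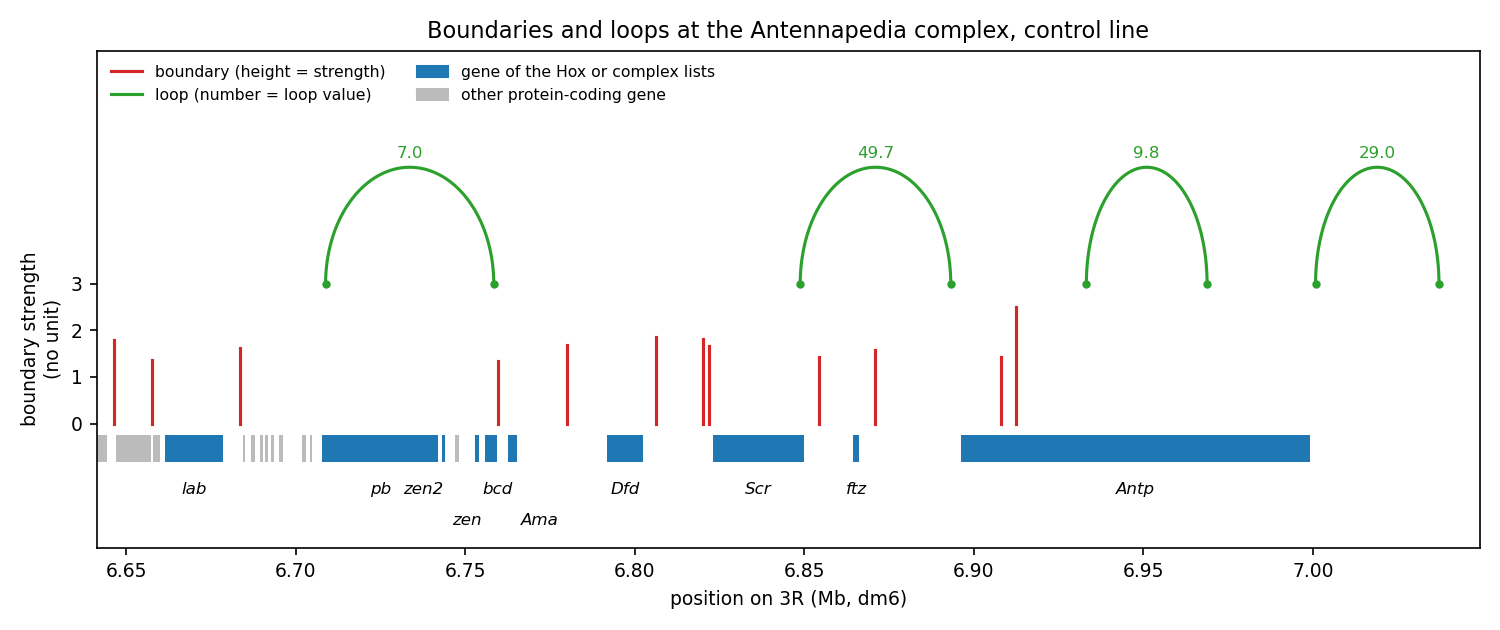
Map of the Antennapedia complex on 3R in the control line, with position in Mb (dm6) on the x axis, genes as boxes, boundaries as vertical lines whose height is their strength (y axis, no unit), and loops as arcs with their values. The loop of value 49.7 joins Scr to the sequence beside Antp and passes over ftz and its 2 flanking boundaries.

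The interval of 3R around the bithorax complex (16636623 to 17022236) held 10 boundaries and 6 loops. This complex holds the Hox genes of the posterior thorax and abdomen, and the interval extends beyond Ubx and Abd-B. The boundaries at 16640001, 16977601, 16988801 and 17002401 and the loop from 17005601 to 17027201 lay in this flanking sequence. Ubx (16656623 to 16734426) had a boundary of strength 2.62 lying 223 bp from its left end and a loop of value 9.05 inside the gene. The strongest boundary, 3.16 at 16798401, lay between Ubx and abd-A (16807214 to 16830049), 8380 bp from the nearest gene end. Abd-B (16927212 to 16972236) took part in loops from the sequence to its left. The loop from 16899201 to 16934001, inside Abd-B, had a value of 18.2 and crossed the boundary at 16919201 (strength 1.54). That boundary bin was itself an anchor, of loops with values of 19.9 and 8.76. Neither abd-A nor Abd-B had an anchor or a boundary within 1 kb of a gene end.

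Away from the Hox genes, some loops joined related developmental genes, 2 of them among the 10 loops of highest value. The loop of highest value with a gene end at each anchor joined H15 and mid on 2L, T-box genes of cardiac and segmental patterning, at 5403601 and 5461201 (57.6 kb, value 128). On X, a loop of value 103 joined disco-r and disco, zinc-finger genes of head and leg development, over 67.6 kb. A loop of 71.4 joined knrl and the gap gene kni on 3L, and a loop of 68.6 joined bab1 and bab2 on 3L, genes of leg and ovary patterning. The homeotic gene tsh and its relative tio on 2L were joined over 196 kb with a value of 60.4, among the 5 longest loops of the map. The anchor at 21899201 on 2L, between tsh and tio and within 1 kb of CG11629, was the only anchor with 3 loops. Its partners lay at tsh, at 22018401 within 1 kb of an end of tio, and at 22024001 inside tio. In all, 19 loops joined the ends of 2 different genes from the developmental lists. None of the 19 spanned a boundary, but neither did 289 of all 313 loops, so this does not set the 19 apart. The 19 included drm with odd (53.4) and with sob (10.3), B-H2 with B-H1 (41.1), esg with wor (24.9), ac with sc (13.9), gcm with gcm2 (13.2) and ara with caup (12.8). The genes Doc1, Doc2 and Doc3 were joined pairwise by 3 loops with values from 5.90 to 11.3. Some of these pairs were named after their values were seen.

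Other loops of high value had 1 gene end or none. Among the 10 highest values, a loop of 101 on 3L had both anchors inside Ptp61F. Its right anchor also lay at rho, a protease gene of EGF signalling that lies within Ptp61F. A loop of 84.4 on 2L, also among the 10, ran from salr, a spalt-family gene, to intergenic sequence 89.2 kb away. A loop of 128 on X had both anchors inside Ten-a, a teneurin gene of synaptic partner matching. It covered 117.6 kb, with its left anchor also near CG15734 and 1 boundary between its anchors. Ten-a and Ptp61F, which have anchors in the gene body, were chosen after their values were seen. A loop of 88.6 on 2R started at hbs, an immunoglobulin-family gene of myoblast fusion. The longest loop, 239.6 kb on 3L from 11247601 to 11487201 with a value of 121, ended at chrb and passed over 15 whole genes. The 2 highest values in the map, 653 on 2L between 23164801 and 23332801 and 317 on 2R between 2647201 and 2740801, lay in the centromere-proximal parts of the arms, and neither loop had a protein-coding gene end within 1 kb of an anchor.

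Developmental genes were concentrated at loop anchors. Of 188 genes in 11 lists of developmental regulators, 66 (35.1%) had an end within 1 kb of an anchor, against 1.69% of the other protein-coding genes. The odds ratio was 31.4, with a 95% interval of 22.3 to 44.1 (Fisher's exact test, adjusted p = 6.16e-63), and 19.6 to 47.9 over the alternatives. The gap and head genes led, with 10 of 14 members at anchors, among them kni and knrl (71.4 each), btd (22.2), ems (17.2) and the Sox gene D (14.7). The odds ratio of this list was 118 (exact test, adjusted p = 1.53e-13), with 58.3 to 155.8 over the alternatives and the lowest within classes of gene spacing. Of the 60 members of paired or clustered transcription factor genes, 33 lay at anchors (odds ratio 62.6, exact test, adjusted p = 1.34e-38, with 30.9 to 103.3 over the alternatives). With loops of at least the median value, the paired factors stood above the gap and head genes (odds ratios 103.3 and 93.9). Of the 10 pair-rule genes, 6 did, namely odd, sob, opa, slp1, slp2 and run, while eve, ftz, prd and hairy (hry in the gene table) did not (odds ratio 69.8, exact test, adjusted p = 8.49e-08). With a gene end required inside the anchor, 1 pair-rule gene remained and the list did not pass (odds ratio 16.3, exact test, adjusted p = 0.18), with odds ratios of 16.3 to 92.7 over all alternatives. Of 32 other developmental transcription factors, 13 lay at anchors (odds ratio 32.6, exact test, adjusted p = 2.33e-13, with 18.8 to 33.7 over the alternatives), led by vvl (62.7), Lim1 (41.6), Awh (15.1), ct (14.5) and gcm (13.2). Of 24 dorsoventral genes, 7 did, including rho, esg, wor, ths and Doc1 (odds ratio 19.2, exact test, adjusted p = 1.85e-06, with 11.3 to 38.7 over the alternatives). Of 18 neural genes, D, ac, sc and dpn did (odds ratio 13.2, exact test, adjusted p = 0.00157, with 7.92 to 23.1 over the alternatives). Of 26 ligands, upd2 (30.4), Pvf3 (17.1), ths (16.5) and Wnt2 (4.86) did (odds ratio 8.41, exact test, adjusted p = 0.00576). Within classes of gene spacing the ligands did not pass (odds ratio 4.53, permutation test within the classes, adjusted p = 0.106), with odds ratios of 4.53 to 15.4 over all alternatives.

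The remaining developmental lists did not pass the test at anchors. Of 11 segment polarity genes, H15 and mid lay at the anchors of their common loop (exact test, adjusted p = 0.0525), and none of wg, hh, en or ptc lay at an anchor. With loops of at least the median value this list passed (odds ratio 20.2, exact test, adjusted p = 0.0147), with odds ratios of 0 to 20.2 over all alternatives. Of 8 Hox genes, Scr was the only one within 1 kb (exact test, adjusted p = 0.302). Within 2 kb, pb (1001 bp from an anchor) and Antp (1573 bp) were added and the list passed with 3 genes (odds ratio 19.6, exact test, adjusted p = 0.00357). The 3 genes lie in the same complex, and the test takes them as independent. With neighbours counted as 1 unit, within 1 kb, 1 of 2 units was at an anchor and the list did not pass (odds ratio 45.8, exact test, adjusted p = 0.0895). Of the 5 other genes of the Antennapedia complex, bcd was at an anchor (exact test, adjusted p = 0.217), and of 16 early zygotic genes of cellularisation and sex determination, run was (exact test, adjusted p = 0.397). The lists overlap, so a gene such as D or H15 counts in more than 1 of them.

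Housekeeping and late tissue-specific genes were rare at anchors. Of 300 housekeeping genes, only RpL6 lay within 1 kb of an anchor (0.333%, odds ratio 0.150, exact test, adjusted p = 0.0272). No gene of the lists of mitochondrial ribosomal proteins (73), proteasome subunits (48) or oxidative phosphorylation (87) did. Of 374 late tissue-specific genes, the chemoreceptor gene Ir48c (73.6) and the odorant-binding gene Obp19d (5.10) did (odds ratio 0.241, exact test, adjusted p = 0.0272), and none of 119 cuticle genes or 25 Osiris genes. Ir48c and the anchor of value 73.6 beside it lie inside ths, a gene of the developmental lists. No single list of either class passed. Both class results rest on few genes and were lost under several alternatives, such as anchors of the loops with at least the median value (odds ratios 0 and 0.236, exact test, adjusted p = 0.124 and 0.198). With neighbouring members counted as 1 unit, at an anchor when any member is, the odds ratios were 0.272 and 0.711 (exact test, adjusted p = 0.41 and 1.00).

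Boundaries showed another gene composition. Of 92 ribosomal protein genes (paralogs included), 59 (64.1%) had an end within 1 kb of a boundary, against 17.9% of other genes, an odds ratio of 8.19 with a 95% interval of 5.25 to 12.98 (Fisher's exact test, adjusted p = 4.45e-21). With the gene end required inside the boundary bin, 21 of the 92 were counted and the odds ratio was 3.91 (exact test, adjusted p = 2.84e-05). RpS15 (boundary strength 2.91), RpS21 (2.72), RpL3 (2.56), RpL30 (2.54) and RpS28a (2.48) stood at the strongest of these boundaries. Mitochondrial ribosomal proteins, with 19 of 73, were not past the threshold (26.0%, exact test, adjusted p = 0.255), with mRpS31 (2.82) and mRpL13 (2.33) at the strongest boundaries. Neither were oxidative phosphorylation genes, with 22 of 87 (25.3%, exact test, adjusted p = 0.255), among them ND-B17 (2.08) and ATPsynF (2.04). Proteasome genes, with 10 of 48 including Rpt3 (1.94) and Rpn9 (1.69), stood at 20.8% (exact test, adjusted p = 0.785). Over the 300 housekeeping genes, 110 (36.7%) were at boundaries (odds ratio 2.67, exact test, adjusted p = 8.66e-14), of which the ribosomal proteins made up 59.

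Late tissue-specific genes were scarce at boundaries, with 21 of 374 (5.61%, odds ratio 0.261, exact test, adjusted p = 1.05e-12, with 0.102 to 0.307 over the alternatives). Neighbours were counted as 1 unit at anchors only, where these 374 genes made 128 units. At boundaries the p-values of this class and its lists thus take clustered genes as independent. Chemoreceptor genes, with 10 of 179, had an odds ratio of 0.263 (exact test, adjusted p = 1.14e-05, with 0.145 to 0.298 over the alternatives), and Ir21a (2.49) and Ir31a (2.32) were at the strongest boundaries. Cuticle genes, with 6 of 119, had one of 0.237 (exact test, adjusted p = 0.000237, with 0 to 0.297 over the alternatives). None of the 25 Osiris genes was at a boundary (exact test, adjusted p = 0.0737, or 0.0252 within 2 kb, which passed), and 5 of 51 odorant-binding genes were (exact test, adjusted p = 0.307). Developmental genes as a class did not differ from other genes at boundaries, with 28 of 188 (14.9%, odds ratio 0.783, exact test, adjusted p = 0.255), and within classes of gene spacing the odds ratio turned to 1.38 (permutation p = 0.172). None of the 14 gap and head genes was at a boundary (exact test, adjusted p = 0.255). Of the other developmental lists, 6 of 60 paired factors, 1 of 10 pair-rule genes, 3 of 11 segment polarity genes and 2 of 24 dorsoventral genes were at boundaries. So were 3 of 18 neural genes, 5 of 32 other factors, 6 of 26 ligands, 2 of 8 Hox genes, 1 of 5 other genes of the complex and 1 of 16 early zygotic genes. None of these lists passed the exact test. Members at the strongest boundaries were Pvf1 (3.18), Ubx (2.62), bin (2.52), gcm2 (2.48), spi (2.41), tup (2.33) and sim (2.24).

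The difference in gene classes between anchors and boundaries was tested directly. Of the 239 genes at an anchor and not at a boundary, 24.3% were developmental, against 0.807% of the 2477 genes at a boundary only. The odds ratio was 39.2, with a 95% interval of 22.7 to 70.5 (Fisher's exact test, p = 2.88e-47). Housekeeping genes made up 0 of the 239 and 4.40% of the 2477 (exact test, p = 7.89e-05). Late tissue-specific genes were 0.418% and 0.807%, too few for the test to tell (odds ratio 0.516, interval 0.0124 to 3.26, exact test, p = 1.00). Another 59 genes lay at both kinds of feature, among them Scr, bcd, odd, mid, disco, gcm2, tup, eya and RpL6.

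**Figure D2:**
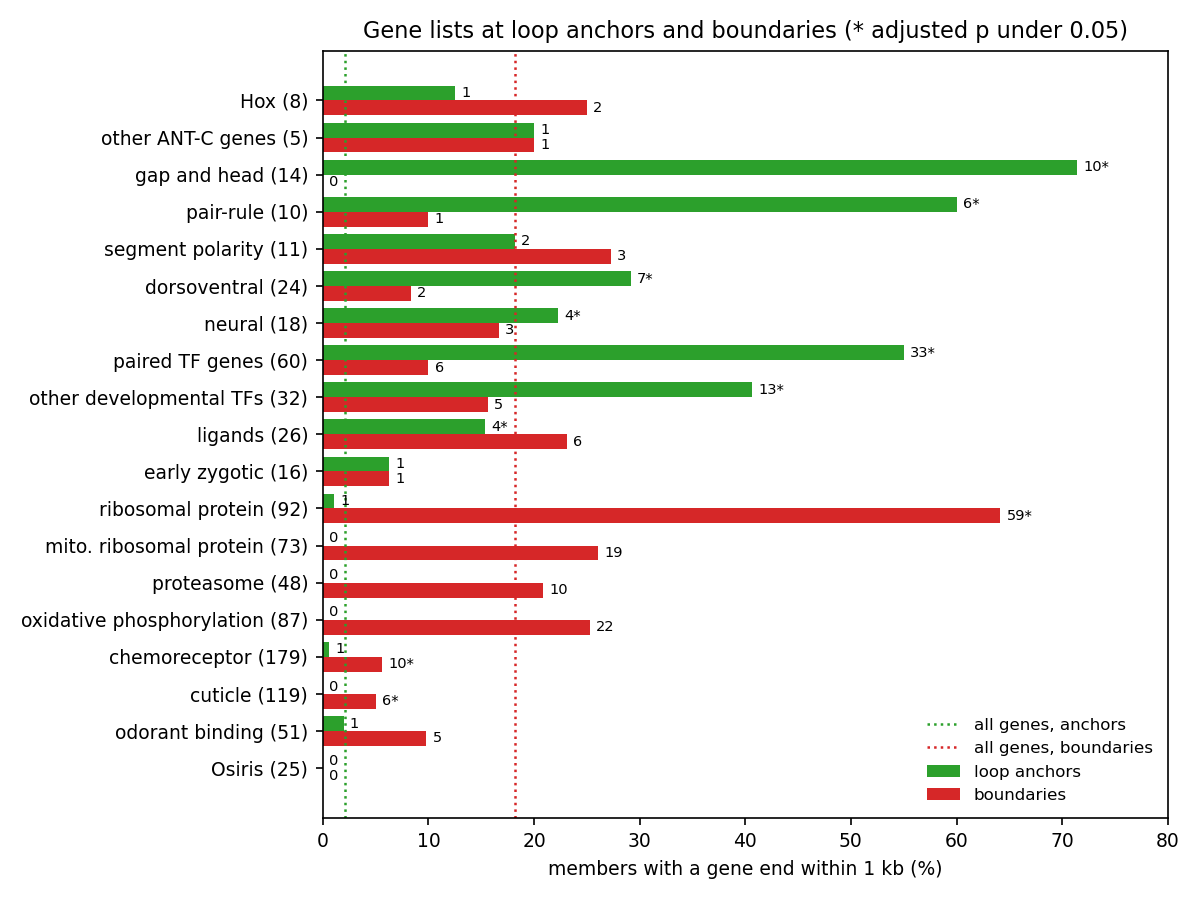
Share of each gene list (percent of members, x axis) with a gene end within 1 kb of a loop anchor or of a boundary, with the number of members in parentheses, the count at the bar's end, and dotted lines for all protein-coding genes. Gap, pair-rule and paired transcription factor genes stand highest at anchors (10 of 14, 6 of 10 and 33 of 60), and ribosomal protein genes at boundaries (59 of 92).

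Boundaries lay at gene ends far more often than shifted boundaries did. Of 1930 boundaries, 1407 (72.9%, 95% Wilson interval 70.9 to 74.8%) had an end of a protein-coding gene within 1 kb, against 27.5% after circular shifts, a ratio of 2.65 (permutation p = 2e-05, the smallest the shifts can give). The ratio rose to 6.28 for gene ends inside the boundary bin itself. Anchors showed a smaller excess, with 256 of them at gene ends (41.7%, 37.9 to 45.6%) against 28.7% after shifts, a ratio of 1.45 (permutation p = 2e-05). The shifts could move anchors into the centromere-proximal parts, where 7 loops lay against 306 elsewhere. The anchor ratio thus does not separate a link to gene ends from loops lying outside these parts. The odds of lying at a gene end were 0.266 times as high for anchors as for boundaries, with a 95% interval of 0.219 to 0.323 (Fisher's exact test, p = 1.14e-43). Outside the centromere-proximal parts the odds ratio was 0.112, with an interval of 0.0892 to 0.140, and over all alternatives it ran from 0.112 to 0.348. The centromere-proximal parts of the arms differed from the rest: 10.3% of 351 boundaries there lay at gene ends, against 86.8% of 1579 boundaries elsewhere. Outside them, 42.4% of 597 anchors did. Of the 10 strongest boundaries on the compared arms, 8 were centromere-proximal, and CG17698 on 3L was the only gene within 1 kb of any of the 10. The other 2, at 5003201 and 5008001 on 3R with strengths of 8.02 and 7.80, lay 7431 and 2631 bp from the nearest gene end, that of plh.

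Loops seldom had a boundary between their anchors. Only 24 of 313 loops (7.67%, Wilson interval 5.21 to 11.2%) did, against 35.9% after circular shifts, a ratio of 0.214 (permutation p = 2e-05). With the anchors included, 269 loops lay wholly inside 1 domain. Both lists describe contacts of the same line, so strong contacts across a bin could count against a boundary there. The shifts break any such link between the calls, so the ratio may in part follow from how the features are defined. The loop at Scr, the loop at Abd-B and the loop from 20643201 to run on X were among the 24, as were loops ending at dac (61.2) on 2L and at Psc (12.2 and 10.4) on 2R. The genes dac and Psc were chosen after their values were seen. Loops that spanned a boundary had a higher median value, 11.9 against 7.58, a difference of 4.29 (permutation p = 0.0483). They were also longer, with a median of 50.0 kb against 31.2 kb (permutation p = 0.0042). With loops permuted within 5 classes of span, the difference in value did not pass (permutation p = 0.347), nor without centromere-proximal loops (difference 2.91, permutation p = 0.147). The mean of the differences within the span classes passed (21.9, permutation p = 0.0101), and also without the centromere-proximal loops (16.9, permutation p = 0.0372), which include the 2 highest values, both of spanning loops. The deposited scores headed APScoreAvg (difference 3.02, permutation p = 0.0245) and RegAPScoreAvg (permutation p = 0.00469) passed too. Both were tested over all loops, without span classes and with the centromere-proximal loops, so the longer span of spanning loops was not adjusted for.

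Few anchors were boundaries themselves. Of all anchors, 21 (3.42%, Wilson interval 2.25 to 5.17%) overlapped a boundary by at least 1 bp, which was 4.15 times the 0.825% found after circular shifts (permutation p = 2e-05). The ratio was 2.03 within 1 kb (permutation p = 2e-05) and 1.19 within 5 kb, where it did not pass (permutation p = 0.0972), and 7.93 for loops of at least the median value (permutation p = 2e-05). The overlapping anchors included those at odd, mid and disco, that of RpL6, and the one near chrb at 11487201 on 3L, the end of the longest loop. Against random gene ends with the same distance to the feature, the expected share was 1.88% and the ratio fell to 1.82 (permutation p = 0.014). The ratio was 1.96 and did not pass with boundaries of at least the median strength (permutation p = 0.239). The 20 boundaries at anchors had a median strength of 1.51, against 1.65 for the others, and this difference of -0.138 did not pass (permutation p = 0.216).

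**Figure D3:**
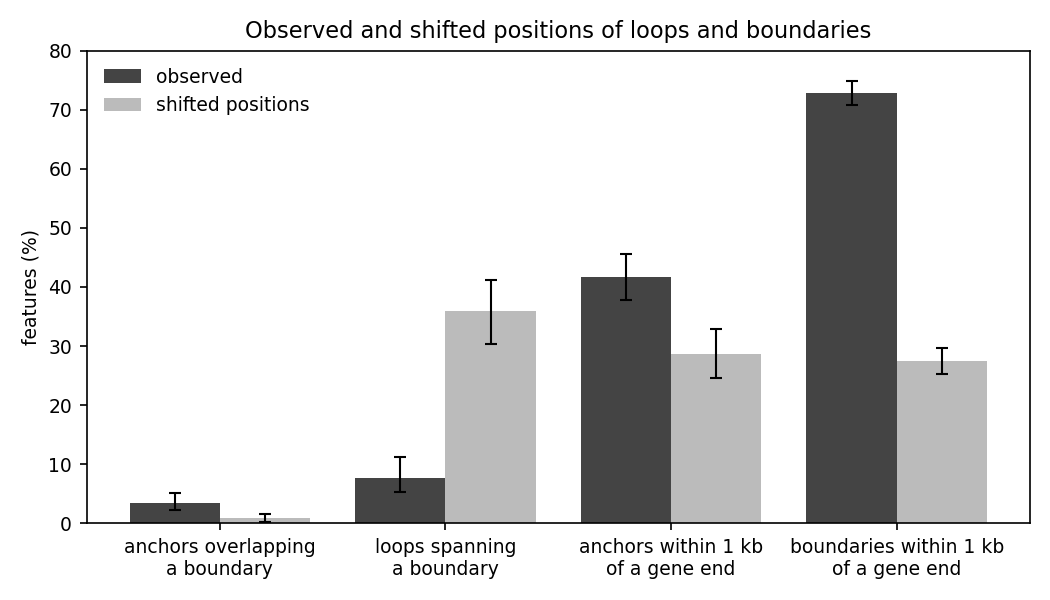
Percent of features (y axis) observed in the control line and after circular shifts along the arm, with 95% Wilson intervals on the observed bars and the 95% range of the shifts on the others. Loops span boundaries less often than shifted loops (7.67% against 35.9%), and boundaries lie at gene ends more often than shifted ones (72.9% against 27.5%).

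Gene ends lay at both anchors of a loop more often than with random partners from the same arm. Both anchors lay within 1 kb of a gene end in 68 loops (21.7%), against 17.4% when partners were permuted within an arm (permutation p = 0.00188). True partners lie near each other, while random partners came from anywhere on the arm. Local gene density was thus not held, and the test cannot tell a preference for pairing from it. A gene end at 1 anchor was found in 122 loops (39.0%) and at neither in 123 (39.3%). Loops with gene ends at both anchors had a median value of 11.1, against 7.89 with 1 and 6.48 with none, and exceeded the rest by 3.66 in the median over all other loops (permutation p = 0.00675). Their median span of 33.6 kb was close to the 30.6 and 34.8 kb of the other classes.

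Across the 313 loops, the deposited value rose with span, with a Spearman's rho of 0.388 (permutation p = 1e-05) and a Pearson's r of 0.498 between log10 values (permutation p = 1e-05). Without the 2 loops farthest from the median span, r was 0.487. The loops are not independent replicates, and the scale of the value is not stated. The values and ranks given for single loops were not adjusted for span.

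**Figure D4:**
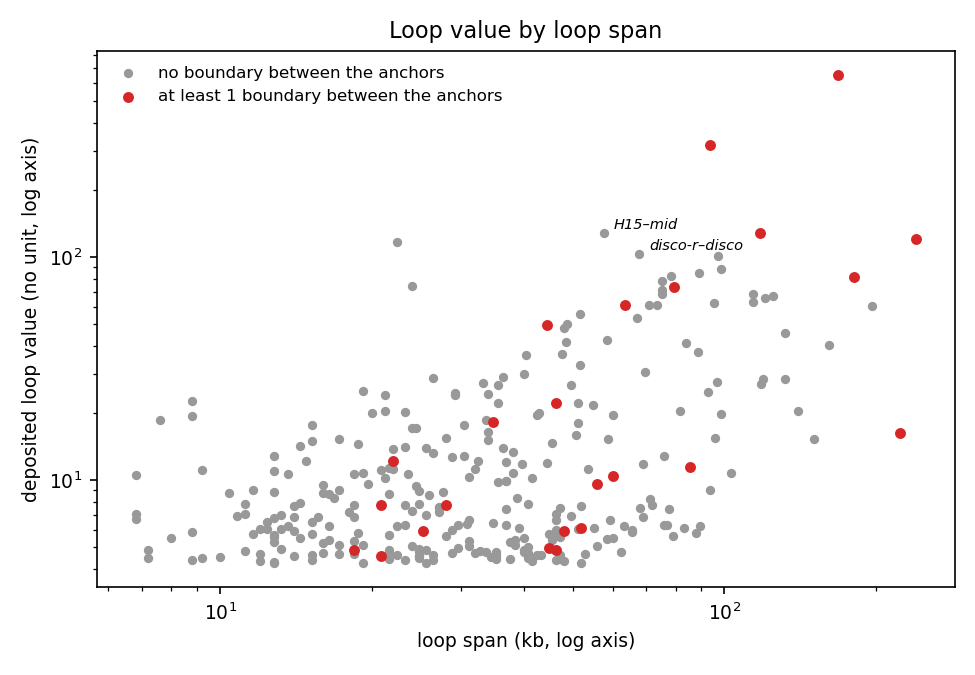
Deposited loop value (y axis, no unit, log axis) by loop span (x axis, kb, log axis) for the 313 loops of the control line, with the 24 loops that span at least 1 boundary in red. Values rise with span (Spearman's rho 0.388), and H15 with mid (128) and disco-r with disco (103) stand out at moderate span.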

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

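The Y chromosome was kept out of the comparisons, yet the list held 90 boundaries there. Their median strength was 2.39, against 1.64 on the compared arms (permutation p = 1e-05) and 1.91 in the centromere-proximal parts of those arms (permutation p = 0.00048). The strongest boundary of the whole list, 10.49, lay on Y at 3566801. No loop was listed on Y, and 2 of its 90 boundaries lay within 1 kb of a protein-coding gene end, with 24 such genes in the table. No explanation for the Y boundaries was tested.

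Of the tests in the next paragraphs, the one of gene ends at boundaries of equal strength was set before its result was seen, though after the position of these boundaries along the arms was known, and the others, with the count per set, after. No biological explanation was tested for these patterns, as the files hold 1 genotype.

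The 66 developmental genes at anchors (odds ratio 31.4) were set against their gene spacing, since genes in wide spaces have fewer neighbours, and against clustering, since neighbours can share 1 loop. Within 5 classes of gene spacing the odds ratio was 19.6, with 8.04 genes expected (permutation p = 2e-05), which argues against spacing as the whole source. With 1 member drawn from each of 105 runs of members within 200 kb, the median odds ratio over 1000 draws was 26.6, with a range of 20.1 to 34.3 (largest exact p = 1.38e-23), which argues against shared loops as the whole source. Clustering of the comparison genes was not adjusted for, and gene length and expression were not tested.

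The 2 highest loop values, 653 and 317, lay next to the centromeres of 2L and 2R. A candidate explanation is erratic scores where few reads map uniquely. A second deposited score of the loop, headed APScoreAvg, was divided by the loop value: the median ratio was 1.89 for the 7 centromere-proximal loops and 0.707 for the other 306, a difference of 1.18 (permutation p = 2e-05). Of the 7, 4 lay outside the 95% range of the others, 0.237 to 1.63. The scores there thus behaved unlike those elsewhere, which goes with this explanation without excluding a true difference in contacts, since no read depth was used.

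Sets of boundaries with exactly equal strength made up 149 of the 2020 boundaries, in 52 sets, and 105 of the 149 lay in centromere-proximal sequence or on Y. All 52 sets lay on a single arm with a median extent of 1.60 kb, 47 of them within 10 kb and 5 beyond, the longest over 96.8 kb. Whether a set is a single boundary entered more than once was not tested, and counting each set once would leave 1923 boundaries. In the distal parts of the arms, 63.6% of 44 such boundaries lay at gene ends against 87.5% of the others, an odds ratio of 0.251 (exact p = 6.53e-05, which takes neighbours in a set as independent). With each set counted once, 10 of 15 lay at gene ends, an odds ratio of 0.286 with an interval of 0.0880 to 1.08 (exact p = 0.0324), so few usable reads as a source goes with the values but rests on few sets and stays open.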

How the results depend on the processing

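No paired analysis was possible because the files hold 1 list for the control line, with no column per sample. Alternatives that left out centromere-proximal features or boundaries of tied strength, that counted neighbours as 1 unit, or that averaged the loop score over span classes were chosen after the data were seen. Neighbours were counted as 1 unit at anchors only, so the gene lists at boundaries have no alternative for clustering. The motif test and its alternatives, and the use of 1 start per gene, were not run. Of 104 alternatives for 20 results, 88 had a p, and 75 of these kept direction and side of the threshold, 1 of them by construction (anchors from the loop table). The other 16 have no p: the number of lists past the threshold ran from 6 to 8 at anchors and 3 to 4 at boundaries, and 4 concern domains. Where centromere-proximal features were removed, the shifts still ran over whole arms, including parts left without targets. This lowers the shifted counts. The ratios then found for anchor overlap (5.11) and for gene ends at anchors (1.51) and boundaries (3.23) are thus raised and say little about robustness. Loops spanning a boundary kept a ratio of 0.147 to 0.261, gene ends at boundaries 1.96 to 6.28, gene ends at anchors 1.31 to 1.65, and developmental genes at anchors an odds ratio of 19.6 to 47.9. Anchor overlap with boundaries lost its call within 5 kb (ratio 1.19) and with the stronger boundaries (1.96). The loop score by spanning lost its call when the same difference of 4.29 was permuted within span classes, and without proximal loops (2.91). It kept it as the mean over span classes (21.9, or 16.9 without proximal loops) and, without span classes, with APScoreAvg (3.02) and RegAPScoreAvg. At anchors, housekeeping genes lost their call at overlap (odds ratio 0.481), within gene spacing classes (0.194), with loops of higher value (0) and as units (0.272), where any member counts. Late tissue-specific genes lost it at overlap (0), with loops of higher value (0.236) and as units (0.711). At boundaries, developmental genes turned from 0.783 to 1.38 within gene spacing classes, past no threshold either way. Of the single lists at anchors, Hox and segment polarity fell to 0 members at overlap (odds ratio 0), pair-rule lost its call at overlap (16.3) and ligands within gene spacing classes (4.53). Hox gained a call within 2 kb (19.6), segment polarity with loops of higher value (20.2), and Osiris at boundaries within 2 kb (0). Boundaries per Mb on X gained a call without proximal parts (1.14). Domains grew to 84.4 kb with the stronger boundaries and 39.6 kb without tied ones, and 21.6% of the former held a loop. The cause was not tested for these changes, except that fewer boundaries make larger domains. Depth is unknown and sets which features were called.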

Other observations

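The tests and counts in this part were all chosen after the data were seen. Other gene kinds near boundaries and near anchors were each compared with shifted features, over 15 tests adjusted together, and the 2 kinds of feature were not tested against each other. Boundaries lay within 1 kb of a snoRNA gene 27 times, 5.64 times the shifted count (permutation test, adjusted p = 6e-05), of a tRNA gene 19 times, 2.81 times the shifted count (permutation test, adjusted p = 0.000686), and of an snRNA gene 6 times, 6.89 times the shifted count (permutation test, adjusted p = 0.00347). Boundaries near lncRNA genes, 104 with a ratio of 0.901, did not pass (permutation test, adjusted p = 0.422). Anchors near lncRNA genes were 88 (14.3%), with a ratio of 2.18 (permutation test, adjusted p = 6e-05). Anchors near tRNA genes had a ratio of 2.79, close to that of boundaries, but with 6 anchors it did not pass (permutation test, adjusted p = 0.0821). Ends of 2 or more genes lay within 1 kb of 54.4% of boundaries against 13.3% after shifts, a ratio of 4.09, but of 8.96% of anchors against 14.1%, a ratio of 0.636 (permutation tests, adjusted p = 6e-05 and 0.00161). The centre of a feature lay inside a protein-coding gene for 50.5% of anchors and 50.9% of boundaries, less than the 67.6% and 67.4% after shifts (permutation tests, adjusted p = 6e-05 for each).

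Loops with both anchors in the same gene were 84 of 313 (26.8%), against 17.7% of shifted loops, a ratio of 1.52 (permutation test, adjusted p = 1e-04). They lay in 76 genes, with 4 in jing and 2 each in Lar, Mnt, Ptp10D, bun, mew and wb. The 2 of Lar also lie in CG46244, a gene that overlaps it. Among those of higher value were loops in Ten-a (128), Ptp61F (101), kirre (33.0), Smr (28.7), pros (25.1) and Dscam1 (24.0). A count of 133 loops (42.5%) had no whole gene between their anchors, and the most was 19. Gene length was not matched in this test.

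Like-named genes were counted after the pairs in the loop table had been seen, so the count describes those pairs and tests nothing. Of the 66 loops that joined ends of different genes, 14 (21.2%) joined genes whose symbols share their first 3 letters, against 2.47% of gene pairs on the same arm at the same distance, a ratio of 8.60. Outside the preset lists these included NetA with NetB (62.1), beat-Vc with beat-Vb (45.9) and comm2 with comm (24.7). Shared letters are only a proxy for shared descent, and pairs such as knrl with kni or H15 with mid are missed.

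Boundary strength was lower at gene ends than elsewhere, 1.61 against 1.82 (permutation p = 1e-05). Outside the centromere-proximal parts the medians were 1.61 and 1.61, a difference of -0.00463 (permutation p = 0.913).

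The domains with the most whole loops held 4 each: one of 328.8 kb on 2L with tsh and tio, one of 147.6 kb on 2L with Pvf2 and Pvf3, and one of 134 kb on 2R that held jing and CG15233 alone.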
